A study of Rattus norvegicus with 10 samples.

How the data were processed

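RNA-seq libraries of prefrontal cortex from 5 control and 5 early life stress (ELS) male Sprague-Dawley rats were compared, 1 library per tissue sample. Per the labels' protocols, total RNA was extracted with a column kit including DNase digestion, and libraries were made with a stranded poly(A)-selecting mRNA kit. The submitters' processing notes name STAR, featureCounts and the rat build rn6, without versions. The alignment settings, the strand setting of the counting, the read layout and the gene annotation release are not given in the sources used here.

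The authors deposited 1 table of 16041 Ensembl rat genes with RPKM-type values for the 10 libraries. Within each gene the values were whole multiples of a step set by a whole gene length and 1 whole total per library, so the table is scaled by library total and gene length only, with no scaling between samples. Whether the deposited unit is RPKM or FPKM is not stated, and RPKM is written throughout. Whole reads, gene lengths and library totals were recovered from these steps for 16015 genes, 100% of those above 0 in any library, with a tolerance of 0.002 reads, and 26 genes were at 0 in every library. Totals were 18838898 to 22311136 reads, of which 71.1% to 73.7% fell in the listed genes. This share was 71.1% to 72.4% in the controls, 71.8% in ELS replicate 2 and 72.9% to 73.7% in ELS replicates 1, 3, 4 and 5. Genes at 0 numbered 385 to 449 in the control libraries and 450 to 504 in the ELS libraries. Neither difference was tested. The listed genes had been filtered by a rule that is not given in the sources used here. Each column name matched 1 sample title, and 0 columns belonged to other samples. Symbols were taken from the table. The reference at hand was of another build, so no coordinates are given. Of the rows, 572 shared a symbol with another row, and 9 had a broken symbol.

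Because the table holds RPKM values, the count test that had been planned was replaced by the test planned for normalized values, before any result was seen. Values were put on the log2(RPKM + 0.1) scale, and 14642 genes with at least 0.5 RPKM in 5 or more libraries were tested, which removed 1399. The limma package (version 3.58.1, R 4.3.3) fitted ELS against control with a mean-variance trend and robust moderation, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The median standard error of a log2 fold change was 0.0976. Reads of stranded libraries counted with an unknown strand setting could be shared between a gene and its antisense or overlapping neighbour, and near-identical copies could share reads too.

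In all, 33 gene lists of cell types, pathways and complexes were fixed before the data were examined, and 732 of their 833 entries were measured. Lists with at least 5 measured members were tested by camera on the same values with a preset correlation of 0.01 between genes, adjusted over the 33 lists. Camera with an estimated correlation, fry, and an exact permutation test of each list's library score over 252 assignments were run beside it. Library totals and principal component scores of the 500 most variable genes were compared by exact permutation tests, two-sided.

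The genes named were set by a rule fixed before the data were examined: the 10 largest changes per direction past the threshold with a mean log2 CPM of at least 1, filled up to 5 per direction by the lowest p where fewer passed; the 5 genes of lowest p per direction; the 3 members of lowest p of each list that passed; up to 3 members per list that passed over all genes or over the list alone; Nr3c1, Nr3c2, Fkbp5, Crh, Crhr1, Bdnf, Fos, Npy and Dnmt3a; and as cell-type examples the 2 members of highest mean. Genes outside it are said to have been chosen after their values were seen, and 71 table rows that met it were followed through the alternatives. A gene that met the rule is not reported here.

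The procedure was tested on simulated reads with the real means and library totals of this comparison, over 14487 genes. It recovered 68% of 100 genes changed by 1.5-fold and 93% of 100 genes changed by 2-fold, with 10 other genes among 171 calls, and made 0 calls when no gene was changed. A simulated list lowered by -0.2 on the log2 scale was found with 0 other lists. The changed genes were drawn only from those above a floor of mean reads. Simulated genes were drawn independently of each other, so spread that many genes share within a library was absent. The recovered shares thus do not cover rare genes or such shared spread, and do not make a count of 0 genes evidence of no change. In the data, the lists that passed had estimated correlations between genes of 0.144 to 0.807. The simulation therefore cannot show how often camera with the preset correlation calls lists falsely here.

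Alternatives were the pseudocount, the filter on low values, the scaling (median of ratios and upper quartile), limma-voom on the recovered reads, scaled by the trimmed mean of M values, with and without sample weights, the moderation without the robust option, the threshold, a replicate number as a block, and leaving out each library in turn. Trimmed-mean scaling of the RPKM values, limma-voom with library totals, library weights on the log2 values, covariates, permuted list scores, and the removal of several libraries together were added after the data were seen. Count models were not run.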

Results

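RNA was sequenced from the prefrontal cortex of adult male Sprague-Dawley rats that had either been reared normally or had gone through early life stress (ELS). The stress was limited nesting, in which the dam and pups are kept with little nest material, and it lasted from postnatal day 2 to postnatal day 9. Tissue was taken at postnatal day 91, so the comparison asks which transcripts differed in the adult cortex long after the stress had ended. There were 5 control and 5 ELS libraries, each from its own tissue sample. The labels did not say whether rats came from different litters, so p-values measure the spread between these tissue samples. Library totals ran from 18838898 to 22311136 reads. They averaged 20861443 ± 1238653 in controls and 19876034 ± 784379 in ELS (mean ± SD, n = 5 in each group), a difference within the spread between libraries (exact permutation test, two-sided, p = 0.175). All gene levels are RPKM, reads scaled by gene length and library total, as mean ± SD over the 5 libraries of a group, and fold changes are ELS against control on the log2(RPKM + 0.1) scale, which understates the change of genes with low values.

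The first principal component of the 500 most variable genes took 24.2% of the variance, and its scores differed between the groups (exact permutation test, two-sided, p = 0.0238). ELS replicate 2 had a score of -10.4, inside the control range of -17.0 to -3.38, while the other ELS libraries lay between 8.49 and 24.96. The second component, with 16.6% of the variance, did not separate the groups (exact permutation p = 0.937) and set control replicate 4 apart at -32.5. The mean chi-square per gene between control replicate 4 and any other control library was 41.1 to 43.6, against 4.92 to 11.05 between the other control libraries.

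**Figure D1:**
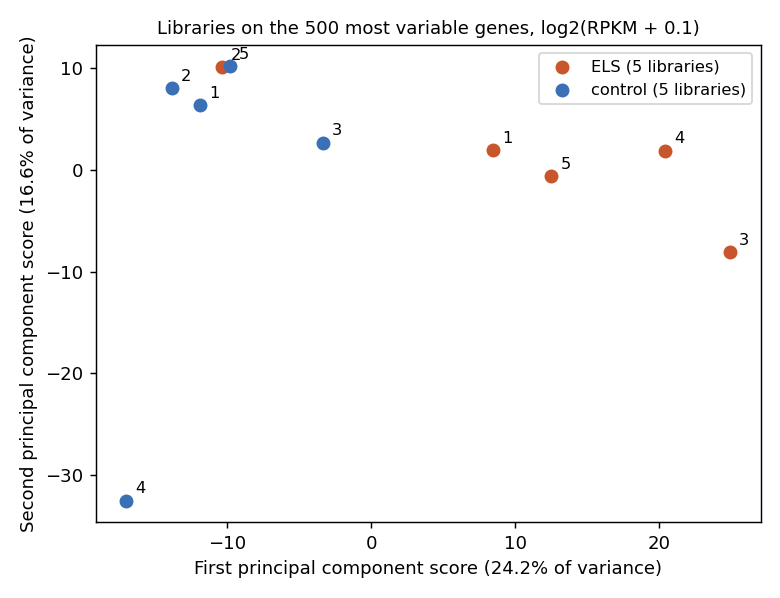
Scores of the 10 libraries on the first (horizontal) and second (vertical) principal component of the 500 most variable genes, in arbitrary units, with replicate numbers beside the points. ELS replicate 2 lies among the controls on the first component at -10.4, and control replicate 4 lies apart on the second at -32.5.

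At the level of single genes, the lowest p-values belonged to genes with modest differences, and none of them passed the adjusted threshold. Id3 (ENSRNOG00000026124), an inhibitor of basic helix-loop-helix transcription factors, was at 23.7 ± 1.58 RPKM in controls and 17.9 ± 0.664 in ELS, a log2 fold change of -0.40 ± 0.05 (SE; limma, adjusted p = 0.112). Igfbp5 (ENSRNOG00000017206), which binds insulin-like growth factors, was at 13.4 ± 1.25 and 9.26 ± 0.491 RPKM, a log2 fold change of -0.52 ± 0.07 (adjusted p = 0.112). The kinase gene Sgk3 had a log2 fold change of -0.54 ± 0.08, Litaf one of -0.60 ± 0.09, and Prima1, which anchors acetylcholinesterase to membranes, one of -0.67 ± 0.11. On the other side, Tmem178a was at 37.2 ± 4.03 RPKM in controls and 50.3 ± 3.45 in ELS, a log2 fold change of 0.44 ± 0.08. The autophagy gene Wipi2 had a log2 fold change of 0.23 ± 0.04, Trim23 one of 0.25 ± 0.05, Tsc2, a brake on mTOR signalling, one of 0.18 ± 0.03, and Baiap2, a postsynaptic scaffold gene, one of 0.20 ± 0.04. In each of these 10 genes all 5 ELS libraries lay beyond every control library on the same side, and the adjusted p of the 8 genes other than Id3 and Igfbp5 was 0.133.

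Over all 14642 genes tested, 0 passed an adjusted p of 0.05 by limma with Benjamini-Hochberg adjustment, and limma-voom on the recovered reads without sample weights also gave 0. At an unadjusted p under 0.05 there were 2988 genes, 1475 higher and 1513 lower in ELS, where 732.1 would arise by chance on average. Genes vary together, so a count without any group effect can lie far from that average. A split with ELS replicate 2 in place of control replicate 5 among the controls gave 2797. The 2 directions parted by size. Among genes with an unadjusted p under 0.05, 385 were lower by at least 1.5-fold and 49 were higher by at least 1.5-fold, a count chosen after the data were seen. The 49 became 81 without control replicate 1 and 98 without control replicate 5, and with a pseudocount of 1 the counts were 203 lower and 20 higher. The share of tested genes with a log2 fold change below 0 was 49.4%, and the median log2 fold change of all genes was 0.00371. The count of 0 depended on how 2 libraries were treated. Without ELS replicate 2 limma gave 444 genes at an adjusted p under 0.05, 136 higher and 308 lower. With all 10 libraries, limma-voom with sample quality weights gave 858, of which 275 were higher and 583 lower, with a weight of 0.169 for control replicate 4 and 0.890 for ELS replicate 2. Without both ELS replicate 2 and control replicate 4, limma gave 1116, of which 513 were higher and 603 lower, a setting chosen after the data were seen.

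Markers of glial cells were lower in ELS. In the list of mature oligodendrocyte and myelin genes, 21 of 21 measured rows had lower means in ELS, with a median log2 fold change of -0.48 (camera with a preset correlation of 0.01, adjusted p = 9.77e-13). Mbp, myelin basic protein, was at 656.8 ± 236 RPKM in controls and 388.3 ± 46.2 in ELS. Cnp, a myelin enzyme, had 114.8 ± 20.6 and 85.1 ± 6.50 RPKM (log2 fold change -0.42 ± 0.11, SE). Of this list 0 rows passed when adjusted over all genes and 20 passed when adjusted over the list alone. The list score, the mean of its centred log2 values, was lower in all 5 ELS libraries than in every control library (0.24 ± 0.31 against -0.24 ± 0.14, exact permutation p = 0.00794, the smallest that 252 assignments can give). Adjusted over the lists, this permutation p was 0.0655. The camera adjusted p of the list was 0.372 with an estimated correlation, which was 0.807. Control replicate 4 held the highest score, 0.77, and without that library the median log2 fold change was -0.34.

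Oligodendrocyte precursor genes had lower means in 9 of 9 members, with a median log2 fold change of -0.30 (camera adjusted p = 5.64e-05, and adjusted p = 0.336 with an estimated correlation). Adjusted over the list alone 6 were lower, among them Sox10, a transcription factor of the lineage, at 10.8 ± 1.85 RPKM in controls and 7.95 ± 0.293 in ELS, and C1ql1 at 9.27 ± 2.49 and 6.08 ± 0.523. The astrocyte list was lower in 15 of 15 members, with a median of -0.20 and a mean of -0.37, or -0.21 without Slc1a2, whose steep fall is described below (camera adjusted p = 2.04e-06, and adjusted p = 0.336 with an estimated correlation). Adjusted over the list alone 7 were lower. The water channel gene Aqp4 was at 80.8 ± 9.22 RPKM in controls and 63.6 ± 4.62 in ELS, and S100b, a calcium-binding protein gene, at 537.2 ± 24.9 and 477.8 ± 23.4. In the microglia list 15 of 15 members had lower means, with a median of -0.20 (camera adjusted p = 5.64e-05, and adjusted p = 0.336 with an estimated correlation), and adjusted over the list alone 2 were lower, C1qb at 17.5 ± 1.12 and 14.3 ± 1.12 RPKM and C1qc at 14.1 ± 1.03 and 11.3 ± 1.34. These encode chains of the complement component C1q. None of the precursor, astrocyte or microglia genes passed when adjusted over all genes.

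**Figure D2:**
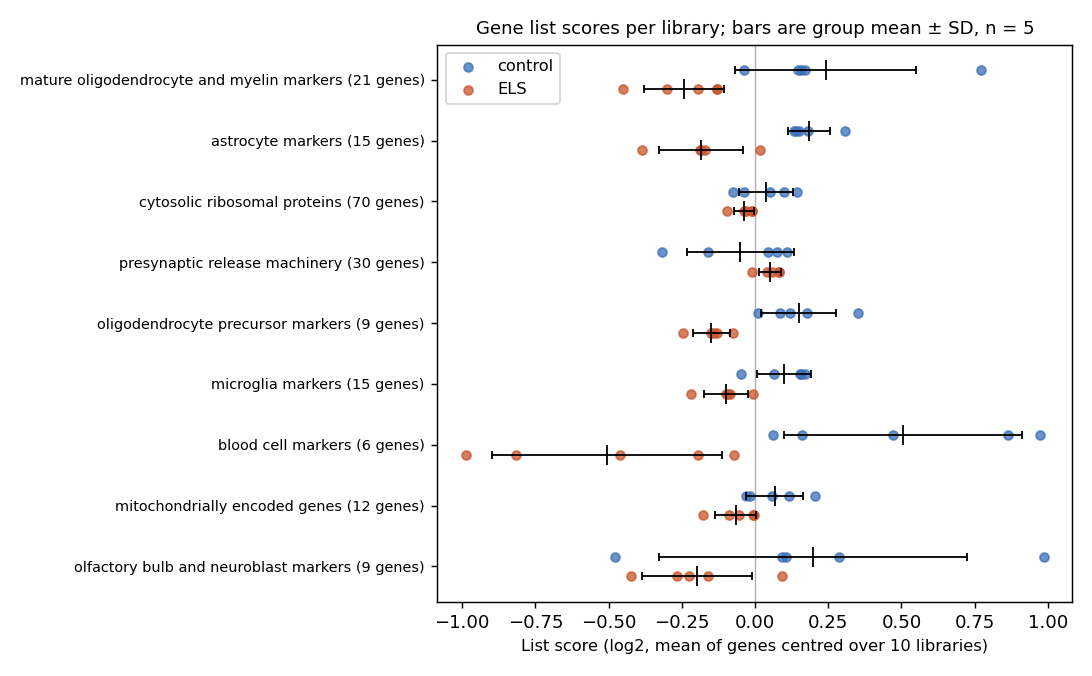
Scores per library (log2, mean of each list's genes centred over the 10 libraries, horizontal axis) for the 9 gene lists past a camera adjusted p of 0.05, with 1 point per library and bars for the group mean ± SD, n = 5. In the myelin, astrocyte, oligodendrocyte precursor and blood cell lists all 5 ELS libraries lie below every control library, and control replicate 4 has the highest myelin score, 0.77.

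Endothelial and pericyte genes had a median log2 fold change of -0.04 with 13 of 14 members lower (camera adjusted p = 0.278), smooth muscle and meningeal genes one of -0.05 (0.535), ependymal genes one of -0.14 (0.278) and choroid plexus genes one of -0.02 (0.465). Without control replicate 4, the endothelial and pericyte list had a median of -0.13 (adjusted p = 0.00686), the smooth muscle and meningeal list one of -0.44 (adjusted p = 0.000775), the ependymal list one of -0.0605 (adjusted p = 0.482) and the choroid plexus list one of -0.207 (adjusted p = 0.272). Striatal projection neuron genes had a median of -0.21 (adjusted p = 0.181), with a score of 1.20 in control replicate 1 and scores of 0.04 or below in the other 9 libraries. Without control replicate 1 this median was -0.000185 (adjusted p = 0.701), and without control replicate 4 it was -0.392 (adjusted p = 0.0196). The olfactory bulb and neuroblast list had lower means in 9 of 9 members, among them Dcx at 6.19 ± 2.13 RPKM in controls and 4.16 ± 0.972 in ELS, with a median of -0.29 (camera adjusted p = 0.0394, and adjusted p = 0.518 with an estimated correlation). Adjusted over the list alone 0 passed. Control replicate 2 had the highest score of this list, 0.99, and without it the median was -0.11 (adjusted p = 0.224), whereas without control replicate 4 it was -0.51 (adjusted p = 0.000775). The call also ended without control replicate 3 or 5 and without ELS replicate 4 or 5 (adjusted p of 0.0511 to 0.0673).

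Transcripts of blood cells were lower in ELS by the widest margin of the 9 lists that passed. The 6 measured rows had a median log2 fold change of -1.07 (camera adjusted p = 5.64e-05, and adjusted p = 0.336 with an estimated correlation), and adjusted over the list alone 5 were lower. Hbb, a beta-globin gene, was at 202.8 ± 70.6 RPKM in controls and 95.1 ± 29.97 in ELS, Hba-a2, an alpha-globin gene, at 380.5 ± 120 and 183.1 ± 59.3, and Alas2, the erythroid enzyme of haem synthesis, at 2.96 ± 1.09 and 1.22 ± 0.540. Globin genes are near-identical copies, so the split of reads between them is uncertain.

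Genes of the presynaptic release machinery were higher in ELS in 25 of 30 members, with a median log2 fold change of 0.19 (camera adjusted p = 4.23e-05, and adjusted p = 0.474 with an estimated correlation). Adjusted over the list alone 9 were higher and 1 was lower, and 0 passed when adjusted over all genes. The synaptic vesicle genes Syn1, Syn2 and Syp were at 209.0 ± 23.7, 98.8 ± 3.35 and 483.8 ± 30.9 RPKM in controls and at 259.7 ± 15.7, 118.5 ± 8.86 and 569.4 ± 29.8 in ELS. The lower member was Rab3c, a vesicle GTPase gene named here after its values were seen, at 23.8 ± 6.52 and 10.8 ± 10.1 RPKM. The library scores of this list did not separate the groups (exact permutation p = 0.357). With the myelin score as a covariate, chosen after the data were seen, the median was -0.00576 (adjusted p = 0.964) with 16 of 30 members lower. That covariate follows the groups and owes 61.9% of its spread within groups to control replicate 4, so this does not tie the rise to myelin. Without that library the median was 0.159 (adjusted p = 2.31e-05), and 0.0569 with the covariate (adjusted p = 0.181). Excitatory neuron genes had a median of 0.19 with 11 of 15 members higher (camera adjusted p = 0.0598), and Fezf2, a transcription factor of deep-layer projection neurons, was at 11.2 ± 1.68 RPKM in controls and 15.3 ± 0.469 in ELS and passed when adjusted over the list alone. Interneuron genes had a median of 0.18 (adjusted p = 0.217), which was 0.0521 without control replicate 4 (adjusted p = 0.661) and 0.274 without control replicate 2 (adjusted p = 0.0837). Without control replicate 4, which had the lowest excitatory neuron score at -0.36, the excitatory list passed with a median of 0.22 (adjusted p = 0.000897). It also passed without control replicate 1 (0.25, adjusted p = 0.0381) and without control replicate 5 (0.21, adjusted p = 0.0411).

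Receptor and channel genes moved in both directions. Of 36 glutamate receptor and postsynaptic genes, 6 were higher and 4 lower when adjusted over the list alone, with a median of 0.10, a mean of -0.06 and a camera adjusted p of 0.228. Grin1, the obligatory NMDA receptor subunit, was at 81.1 ± 1.67 RPKM in controls and 93.8 ± 5.83 in ELS (log2 fold change 0.21 ± 0.05, SE), whereas the NMDA receptor subunit Grin2a was at 9.16 ± 3.24 and 3.65 ± 3.18 (log2 fold change -1.52 ± 0.44, SE). Grin2a was at 9.27 RPKM in ELS replicate 2 and at 1.61 to 2.86 in the other ELS libraries. It belongs to the set of steep falls described below, as does Cacna1e, the lower member of the channel list that follows. Of 43 potassium, sodium and calcium channel genes 3 were higher and 1 was lower when adjusted over the list alone (median 0.08, mean -0.06, camera adjusted p = 0.278), with Kcnq5 at 23.7 ± 1.01 and 28.4 ± 1.63 RPKM. Of 26 monoamine and acetylcholine receptor genes 3 were higher, among them the muscarinic receptor gene Chrm3 at 14.2 ± 0.545 and 17.5 ± 1.70 RPKM, and 1 was lower, Adra2c at 7.68 ± 1.56 and 5.75 ± 0.260 RPKM (median 0.11, camera adjusted p = 0.228, counts adjusted over the list alone). The median was 0.0442 without control replicate 4 (adjusted p = 0.627), 0.0721 without ELS replicate 3 (0.207) and 0.221 without control replicate 1 (0.0906). The list of GABA receptors and inhibitory synapse genes had 2 higher members adjusted over the list alone (median 0.07, mean -0.03, adjusted p = 0.228).

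A set of genes was far lower in 4 ELS libraries and at the control level in ELS replicate 2. Slc1a2 (ENSRNOG00000005479), the main glutamate transporter of astrocytes, was at 127.7 to 275.7 RPKM in the controls and at 35.9, 14.2, 13.6 and 29.3 RPKM in ELS replicates 1, 3, 4 and 5, but at 231.5 in ELS replicate 2. Its gene model in the table was 882 bases long. The calcium channel gene Cacna1e was at 7.28 to 14.4 RPKM in controls, at 11.4 in ELS replicate 2 and at 0.603 to 1.99 in the other ELS libraries. Grin2a and Psd3 followed the same order, Psd3 being named here after its values were seen. With all 10 libraries the adjusted p of Slc1a2 was 0.133 (log2 fold change -2.59 ± 0.68, SE), and without ELS replicate 2 it was 0.00686 (log2 fold change -3.28), the lowest of a range up to 0.294 when each library was left out. Over the 385 genes lower by at least 1.5-fold, 70.4% were at or above the lowest control library in ELS replicate 2, against 15.6%, 5.97%, 9.87% and 10.4% in ELS replicates 1, 3, 4 and 5. These 385 genes were mostly of low abundance, 177 of them lying in the lowest of 4 equal bins of mean expression and 30 in the highest.

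**Figure D3:**
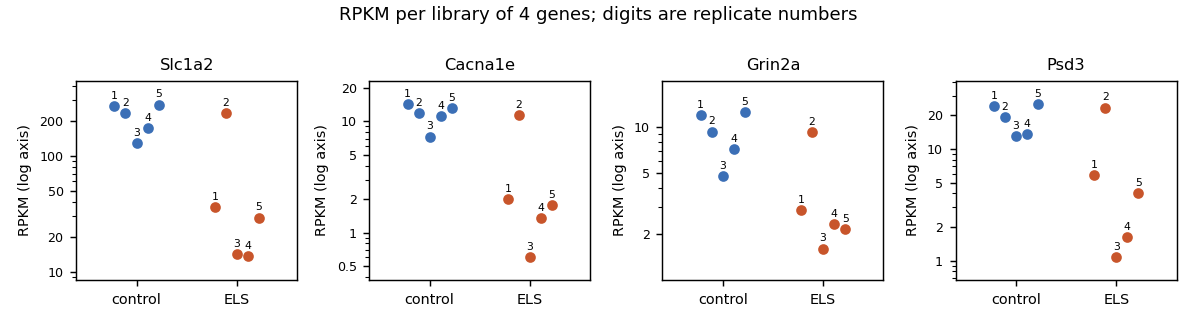
RPKM (vertical log axis) of Slc1a2, Cacna1e, Grin2a and Psd3 in the 5 control and 5 ELS libraries, 1 point per library with its replicate number. ELS replicate 2 lies within the control range in each panel, at 231.5 RPKM for Slc1a2, while ELS replicates 1, 3, 4 and 5 lie below every control.

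Among housekeeping complexes, cytosolic ribosomal protein genes had lower means in 62 of 70 members, with a small median of -0.09 (camera adjusted p = 3.42e-06, and adjusted p = 0.5002 with an estimated correlation). Adjusted over the list alone 0 passed. With the myelin score as a covariate, chosen after the data were seen, the median was -0.0233 with 38 of 70 members lower (adjusted p = 0.538), and without control replicate 4 it was -0.0773 (adjusted p = 4.08e-05), or 0.0117 with that covariate (adjusted p = 0.475). Rpsa was at 145.0 ± 7.29 RPKM in controls and 127.8 ± 4.98 in ELS. Mitochondrially encoded genes were lower in 11 of 12 members, with a median of -0.13 (camera adjusted p = 0.000498, and adjusted p = 0.5002 with an estimated correlation), and adjusted over the list alone 3 were lower, with Mt-nd1, a subunit of respiratory complex I, at 6894 ± 287 and 5866 ± 252 RPKM. The nuclear genes of oxidative phosphorylation had a median of 0.01 over 74 members (adjusted p = 0.609). Heat shock and protein folding genes had a median of 0.03 (adjusted p = 0.487).

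Genes of the stress hormone axis did not differ between the groups beyond the spread between libraries. The list of stress-hormone and neuropeptide signalling genes had a median log2 fold change of -0.02 and a mean of 0.04 over 15 members (camera adjusted p = 0.994), and 23 glucocorticoid-responsive genes had a median of -0.02 (adjusted p = 0.726). Nr3c1, the glucocorticoid receptor, had 2 rows in the table. The longer model, of 5078 bases, was at 14.4 ± 1.35 RPKM in controls and 14.0 ± 0.707 in ELS (log2 fold change -0.03 ± 0.07, SE, adjusted p = 0.821), and the shorter one, of 1239 bases, at 10.7 ± 2.01 and 9.49 ± 1.64 (adjusted p = 0.559). Nr3c2, the mineralocorticoid receptor, was at 9.76 ± 8.05 and 5.86 ± 0.390 RPKM (adjusted p = 0.496), with 24.1 in control replicate 4 and 4.66 to 6.99 in the other controls. Fkbp5, a co-chaperone induced by glucocorticoids, was at 10.4 ± 3.67 and 10.4 ± 1.48 RPKM (adjusted p = 0.906). Crh, corticotropin-releasing hormone, was at 2.40 ± 1.11 and 2.93 ± 0.237 (adjusted p = 0.513), and its receptor Crhr1 at 7.52 ± 3.26 and 10.02 ± 0.705 (adjusted p = 0.410). Control replicate 4 was the lowest library for both, at 0.600 RPKM of Crh and 1.80 of Crhr1. With each library left out, the log2 fold change ran from 0.0521 to 0.637 for Crh and from 0.162 to 0.762 for Crhr1. The growth factor gene Bdnf was at 3.31 ± 1.52 and 3.40 ± 0.284 (adjusted p = 0.780), the immediate early gene Fos at 14.0 ± 7.78 and 13.8 ± 4.81 (adjusted p = 0.899) and the DNA methyltransferase gene Dnmt3a at 6.99 ± 0.510 and 6.60 ± 0.510 (adjusted p = 0.534). Npy was not analysed here. The 37 immediate early genes had a median of -0.07 (camera adjusted p = 0.968). It was 0.0550 without ELS replicate 2 (adjusted p = 0.375) and -0.143 without control replicate 4 (0.224). The median of the glucocorticoid-responsive genes was 0.0631 without ELS replicate 2 (0.680) and 0.00999 without control replicate 4 (0.848).

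**Figure D4:**
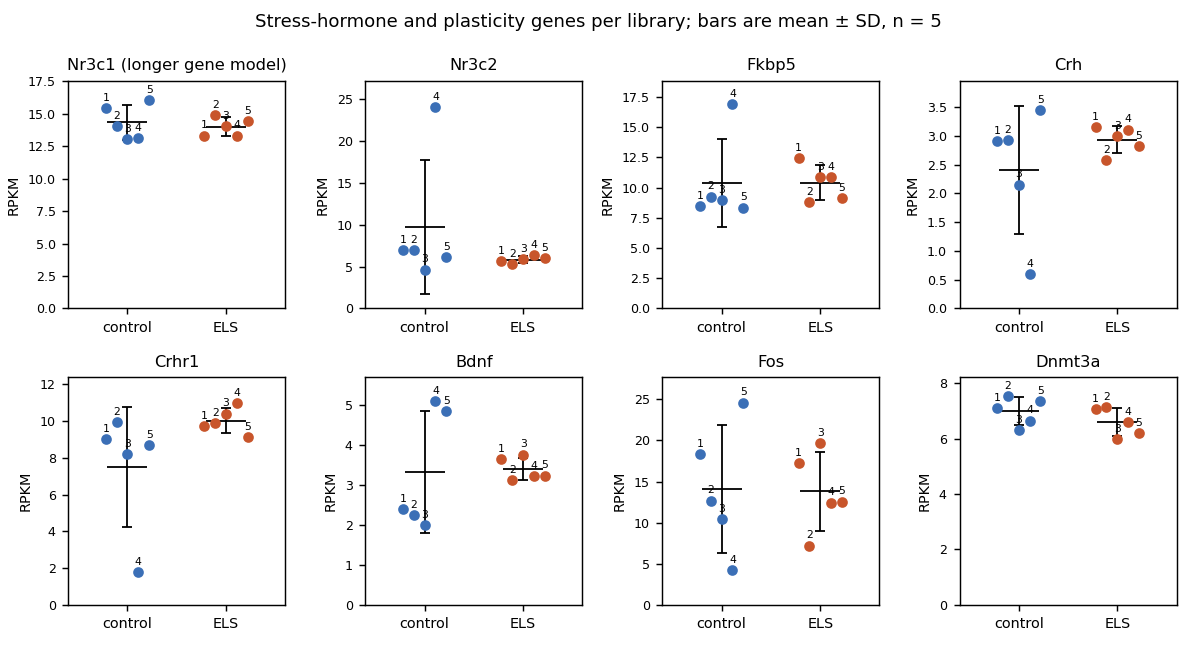
RPKM (vertical axis, from 0) of 8 stress-hormone and plasticity genes in each library, with replicate numbers and bars for the group mean ± SD, n = 5. The groups overlap in every panel, and control replicate 4 lies apart for Nr3c2 at 24.1 RPKM, for Fkbp5 at 16.9 and for Crhr1 at 1.80.

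With all 10 libraries, the lists of signalling and regulatory genes that remained did not pass, and 4 of them passed when single libraries were left out. Perineuronal net and extracellular matrix genes had a median of -0.16 (camera adjusted p = 0.0539), with Ptprz1 and Hapln2 lower when adjusted over the list alone. This list passed without control replicate 1 or 2 and without ELS replicate 2 or 3 (adjusted p of 0.0191 to 0.0451), and its median was -0.0251 without control replicate 4 (adjusted p = 0.0927) and -0.10 without ELS replicate 2. Neurotrophin and growth factor genes had a median of -0.24 (0.0608), cytokine and innate immune genes one of -0.14 (0.0964), and interferon and antigen presentation genes one of -0.15 (0.0999). Without control replicate 4 these 3 lists passed, with medians of -0.118 (adjusted p = 0.0346), -0.160 (0.01597) and -0.177 (0.01597). The neurotrophin list also passed without control replicate 3 (adjusted p = 0.0366) and without ELS replicate 2 (0.0424), with a median of -0.119 without ELS replicate 3 (0.0736) and of -0.157 without ELS replicate 5 (0.0606), and the interferon list passed without ELS replicate 1 (0.0277). Without control replicate 1 or 2 the cytokine median was -0.0840 or -0.0624 and the interferon median -0.0940 or -0.0650, and without ELS replicate 2 the interferon median was -0.0539, none of them past the threshold. The microRNA machinery had a median of -0.08 (0.181), with Ago2, the slicer of the pathway, at 5.57 ± 1.24 RPKM in controls and 3.01 ± 1.53 in ELS. Ago2 was at 5.59 RPKM in ELS replicate 2, inside the control range of 3.58 to 6.72, and at 1.48 to 2.80 in ELS replicates 1, 3, 4 and 5. In that list 1 gene, Ran, was higher and 3 were lower when adjusted over the list alone. Of 40 DNA methylation and histone modification genes 0 passed when adjusted over the list alone, with a median of -0.02 (0.326). Circadian clock genes had a median of 0.14 (0.465), with Hlf, a clock-output transcription factor, at 28.0 ± 5.11 and 40.6 ± 4.08 RPKM, higher when adjusted over the list alone. Cell adhesion and axon guidance genes had a median of -0.02 (0.714).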

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

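The tests of a wrong label, of a library property, of length as the whole cause, of control replicate 4, of white matter and of neurons for the myelin part, and of blood, and the myelin or glial minus endothelial differences and list positions with each library left out, and the myelin covariate without control replicate 4, were chosen after the results were seen. Those of the length percentile, of white matter for the astrocyte part and of neurons for the other glial lists were written before.

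In 23 of 210 groups of 5 library values, 1 library lay far from the other 4, where chance alone flags about 1 in 20, or 10.5 of them. Control replicate 4 accounted for 13 and ELS replicate 2 for 7. In control replicate 4 the list scores were 0.773 for myelin, against 0.170 or below in the other controls, 0.309 for astrocytes, 0.735 for ependymal cells, -0.225 for endothelial cells and pericytes and -0.663 for monoamine and acetylcholine receptors. That library also had 1065.7 RPKM of Mbp, against 467.7 to 635.1 in the other controls, 95.1 of Tf, 24.1 of Nr3c2, 16.9 of Fkbp5 and 10.4 of Adra2c. Its levels were low for Crhr1 at 1.80 RPKM, against 8.20 to 9.92, for Ran at 82.9 and for Syn1 at 167.7. Control replicate 3 stood low in the scores of microRNA machinery, at -0.0178, and of cell adhesion and axon guidance, at -0.133.

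In ELS replicate 2 the values that stood apart from the other ELS libraries were 231.5 RPKM of Slc1a2, 11.4 of Cacna1e, 9.27 of Grin2a and 1.69 of Sox11, which were high, and 14.4 of Fezf2, which was low. Its list scores stood high for perineuronal net and extracellular matrix genes, at 0.0345, and low for interferon and antigen presentation genes, at -0.402. In ELS replicate 4 Rps16 was low at 48.4 RPKM, against 51.0 to 51.6.

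The first pattern weighed is the steep fall of Slc1a2, Cacna1e, Grin2a and others in 4 of the 5 ELS libraries. The 113 genes called lower by more than 1 log2 unit without ELS replicate 2 had a median annotated length of 3213 bases. Matched random sets had one of 1891 (percentile 100). But 7076 other genes in the same annotated length range had a median log2 change of 0.0270 (quartiles -0.11 and 0.13). These values argue against annotated length as the whole cause. Lengths of the transcripts themselves were not at hand, so the values do not speak to those. A property of the libraries that also varies without stress, such as RNA integrity or coverage along transcripts, may contribute. The 31 genes picked within the ELS libraries alone spread by 0.892 log2 units between the control libraries, with control replicates 3 and 4 at -0.77. The spread was at most 0.351 in 10000 random sets matched on expression. The 31 genes were picked for moving together and the random sets were not. The spread thus shows that these genes also vary among the controls, but not from which source. A wrong label on ELS replicate 2 cannot be told apart from a library property, because its median position in rising genes chosen without it was 0.369 (0 is control, 1 is ELS) and the controls treated the same way reached from -0.60 to 0.642. The list scores left it open too. Over the 11 lists that passed without it, its median position was 0.501, against -0.489 to 0.769 for the controls treated the same way, and it lay beyond every control in 4 of these lists and inside the control range in 7. An effect of limited nesting that 1 rat did not show stays open and untested, since the 4 low libraries are all ELS.

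The second pattern is the lower level of glial marker lists in ELS. Control replicate 4 alone does not account for it, as the median of the myelin list without that library was -0.341. For myelin minus endothelial genes, a score was taken from list medians and not from the means used above. It differed between the groups (0.21 ± 0.43 in controls, -0.21 ± 0.12 in ELS, exact permutation p = 0.0159). Measured by list medians only, the values argue against more neurons alone for the myelin part. The difference of mean scores was not tested, and it ordered the libraries otherwise. Control replicate 1 had mean scores of -0.0377 for myelin and 0.129 for endothelial cells and pericytes, against -0.130 and -0.0405 in ELS replicate 3. Its difference of mean scores lay below those of ELS replicates 1, 2 and 3, so the inference does not extend to mean scores. In the score from list medians, control replicate 4 made up much of the gap between the groups, at 0.967 against -0.125 to 0.133 in the other controls. Without it the difference went from -0.421 to -0.232 (exact permutation p = 0.0317), with control replicate 1 at -0.125 below ELS replicate 3 at -0.0407, and with each library left out p ran from 0.00794 to 0.0476. For the other glial lists the same comparison gave an exact permutation p of 0.0873 for a difference of -0.168, which was -0.0805 without control replicate 4 (p = 0.167), and p ran from 0.0159 without control replicate 5 to 0.214 without ELS replicate 5, which leaves a larger neuron share open. A smaller share of white matter in the ELS tissue pieces cannot be told apart from an effect of stress on oligodendrocytes, because nothing in the table records the dissection, and the exact permutation p of the myelin score, 0.00794, restates the fall without separating the 2. With the myelin score as a covariate the astrocyte median went from -0.20 to -0.0594 (adjusted p = 0.221), between the bounds set beforehand. The astrocyte difference between the groups may thus or may not follow the same axis. The precursor median went from -0.305 to -0.117 (adjusted p = 0.330), which ended that call too, while the microglia list kept its call at -0.142 (adjusted p = 0.00966). Without control replicate 4 the covariate gave 0.00877 for astrocytes (adjusted p = 0.889), -0.137 for precursors (0.473) and -0.0648 for microglia (0.394). Within groups, the astrocyte score ran with the myelin score, at a correlation of 0.686, or 0.707 without control replicate 4. For precursors it was 0.939, or 0.833 without that library, and for microglia 0.0477, or 0.405. The covariate itself follows the groups, with 56.1% of its variance between them, so it cannot part white matter from stress.

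The third pattern is the lower level of blood cell transcripts. Residual blood in the tissue is a candidate source, since over the 10 libraries the SD of log2 Alas2 over Hbb was 0.353 times that of log2 Hbb, so that an erythroid enzyme gene and globin moved largely together. Differences in perfusion, bleeding at collection or blood volume after early stress were not tested.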

How the results depend on the processing

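The settings with library weights on log2 values, covariates, several libraries left out together, permuted list scores, trimmed-mean scaling, and voom with library totals, and the 1.5-fold counts, were chosen after the data were seen. The cause of a change was not tested unless stated.

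The count of 0 genes at an adjusted p under 0.05 held under every scaling, filter and pseudocount, under limma-voom without sample weights, at an adjusted p under 0.10, and with the steep-fall covariate. It was 858 (275 higher, 583 lower) by voom with sample quality weights and 866 (374 and 492) with library weights, both of which gave control replicate 4 the lowest weight, 0.169 and 0.185, and shared 710 genes. The first residual component as a covariate, which is built to take up spread within groups and so makes p too small, gave 1544 (932 and 612). Removing control replicate 4 and ELS replicate 2 gave 1116 (513 and 603). The myelin covariate gave 1 lower gene, Tnnt2, and an unadjusted p under 0.05 gave 2988 (1475 and 1513). Leaving out each library gave 0 to 444 genes, 0 to 136 higher and 0 to 308 lower: 444 without ELS replicate 2, 1 (the ribozyme row Hammerhead_HH9) without ELS replicate 5, and 0 otherwise.

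The 385 genes lower by 1.5-fold became 203 with a pseudocount of 1, which shrinks low genes, 183 with the steep-fall covariate and 143 without control replicates 1, 2 and 4, and were 292 to 529 with each library left out. The 49 higher genes became 77 with no filter, 24 with the CPM filter, 20 with a pseudocount of 1, 149 with the residual component, 135 with the myelin covariate, 74 without control replicates 1, 2 and 4, and 34 to 98 with each library left out (81 without control replicate 1, 98 without control replicate 5). The share below 0 was 51.8% with upper-quartile scaling, 46.7% without control replicate 4 and ELS replicate 2, 46.8% without control replicates 1, 2 and 4, and 47.9% to 50.3% with each library left out.

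The 9 lists past the threshold became 14 with either kind of library weights, 15 without control replicate 4 and ELS replicate 2, 16 without control replicates 1, 2 and 4, 4 with fry, 0 with an estimated correlation and 0 by exact permutation of scores, and 8 to 16 with each library left out (16 without control replicate 4). The presynaptic median turned to -0.00576 with the myelin covariate (adjusted p = 0.964; 3.93e-06 to 0.000612 with each library left out), and that covariate also ended the calls of the myelin, precursor, astrocyte and ribosomal lists, the myelin call by construction. It moved other lists with it, to -1.07 for smooth muscle (adjusted p = 2.28e-12), -0.971 for striatal neurons (0.000214), -0.255 for interneurons (0.00966) and -0.242 for endothelial cells (0.000363), and owes 61.9% of its spread within groups to control replicate 4. Over all settings the 9 lists kept direction and side of the threshold 241 times and lost the call in the same direction 27 times. With the CPM filter the blood list had too few genes for a value.

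Of the 71 named rows, 0 were past the threshold in the main setting, 49 with voom quality weights and 29 without ELS replicate 2. In the planned settings signs turned for Fos, Fkbp5, Bdnf, Cd24 and the longer Nr3c1 model: Fos was -0.184 with voom quality weights and -0.256 to 0.375 with each library left out, and on leaving out each library Fkbp5 ran from -0.0188 to 0.236, Bdnf from -0.00398 to 0.322, Cd24 from -0.129 to 0.0190 and the longer Nr3c1 model from -0.0636 to 0.0106. Among the settings added later, the myelin covariate turned 7 signs, of Fos, Cd24, Crh, Crhr1, Nr3c2, Olig1 and Apoe (-0.217 to 0.0508), the steep-fall covariate 5, library weights 2, the removal of control replicates 1, 2 and 4 turned 2 and that of control replicate 4 and ELS replicate 2 turned 1.

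With the replicate number as a replicate block, 0 genes passed and 10 lists did. Same-numbered libraries correlated at -0.03, 0.07, 0.06, -0.08 and 0.04, and 1 of 5 control libraries correlated best with its own number. The values thus gave no sign that the numbers pair the rats, but they cannot exclude it. Exact permutation p of library totals stayed between 0.103 and 0.365 with each library left out. Models of counts and their surrogate variables were not run. The plan set another test for a table of RPKM values, although the recovered whole reads would have allowed count models. Scaling by library total alone is the main setting. At 18838898 reads or more, 1 read in a gene of the median length of 2079 bases is far below the filter of 0.5 RPKM, so depth limits mainly the short and rare genes.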

Other observations

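The splits into other groups of 5 were tests written before their results were seen. Chance cannot be excluded for the number of gene lists: 50 of 100 splits of the 10 libraries gave 9 or more lists past the camera threshold, with 17 in the highest other split. Nor can it for the share of genes on the larger side of 0, 50.6% in the real split, which 78 reached (highest other 55.7%). The 2988 genes at an unadjusted p under 0.05 were reached by 1 of 100 splits, the real one. The highest other split, with control replicates 1, 2, 3 and 4 beside ELS replicate 2, gave 2797. Chance is thus unlikely for this count, but it is not excluded, since not every possible split was run. The 1.5-fold counts were picked from the real grouping, so the splits are given for them without a statement on chance: 2 of 100 reached the 385 lower genes as the larger of their 2 directions (highest other 406), and 2 reached the 434 in either direction (highest other 439). For the count of 0 genes at an adjusted p under 0.05 the splits give no test of chance, since all 100 must reach 0. Of the 100 splits, 15 gave at least 1 such gene, where the real grouping gave 0. The most, 35, came from a split with ELS replicate 2 beside control replicates 1, 2, 3 and 5. That split with 35 genes, in which control replicate 4 changed sides with ELS replicate 2, also gave the 406, and points to a structure of the libraries that the groups do not follow.

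Without ELS replicate 2, the gene of lowest adjusted p was Map2, a neuronal cytoskeleton gene, with a log2 fold change of -0.66 (adjusted p = 0.000532 in that setting and 0.133 with all 10 libraries). It was chosen after its values were seen. In the same setting Chrm1, Chrm3, Grin1, Syn2 and Kcnq5 had log2 fold changes of 0.26, 0.35, 0.24, 0.30 and 0.29, and the position of ELS replicate 2 between the control level of 0 and the level of the other ELS libraries at 1 was 0.085, 0.217, 0.330, 0.301 and 0.511 for these 5 genes. It was nearer the ELS level for Tsc2, Tmem178a, Wipi2, Trim23 and Fezf2, at 0.592, 0.688, 0.739, 0.775 and 0.796, and for the falling genes Igfbp5, Id3, Litaf and Sgk3, at 0.817, 0.866, 0.970 and 1.06, but not for Baiap2 at 0.422, all 10 named from tests that included this library. The median over the 136 rising genes was 0.369 (quartiles 0.199 and 0.539), and over the 308 falling genes -0.00794.

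Small RNA loci (426 tested) had a median log2 fold change of -0.15, at percentile 15.3 of random sets matched on expression, whose median was -0.12. Over 4 equal bins of mean expression, the median log2 fold change of all genes went from -0.08 in the lowest over -0.04 and 0.02 to 0.06 in the highest.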
